A study of Homo sapiens with 6 samples.

How the data were processed

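RNA was measured in 6 libraries from formalin-fixed, paraffin-embedded human liver tissue of 2 cases of the solid-tubulocystic variant of intrahepatic cholangiocarcinoma, a bile duct type cancer that grows inside the liver. Tissue areas were macro-dissected, that is, scraped from sections under visual guidance, and RNA was extracted with a kit that recovers DNA and RNA from the same fixed material, per the labels' protocols. Libraries were made with a target enrichment kit (SureSelectXT Low Input), in which baits pull down chosen sequences before sequencing, and were read as single-end reads on a NextSeq instrument to an intended depth of 30 M reads, per the labels' protocols. The baits, the RNA integrity of each piece and the strand setting of the counting are not given in the sources used here.

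The deposited files were 1 table per library with 61487 features in the same order. Expected counts, which need not be whole because reads that match several genes are split among them, were deposited by the authors in the layout of RSEM gene results, per the file headers. TPM values (scaled to gene length and library total) were deposited beside them by the authors, per the file headers. FPKM values (the older unit scaled in the same way) were also deposited, per the file headers, and were not used here. The same tables held a gene length and an effective length per feature, the other deposited columns, which differed by 74.9 bases. The submitters' processing notes name Trim Galore, HISAT, SAMtools, HTSeq and the hg38 build, with no versions, whereas the deposited tables have RSEM's columns; the RSEM version and the gene annotation are not given in the sources used here. Of the 61487 features, 40821 carried a gene symbol and 58312 matched the GENCODE release 29 annotation of GRCh38 by Ensembl identifier. That annotation supplied positions, gene types and coding lengths.

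Splitting of shared reads affects genes with near-identical relatives. Values of the metallothionein genes, SAA1 and SAA2, HBA1 and HBA2, HSPA1A and HSPA1B, and the HLA genes are uncertain for that reason. Whether CLEC4G and CLEC4M are alike enough to share reads was not examined, so caution applies to their values too. Antisense and overlapping genes are uncertain as well, because no source states that strand was used. Captured counts depend on bait efficiency, so levels of different genes within a library are not comparable as molecule numbers. Ratios of the same gene between libraries are free of that limit, but not of differences in genomic DNA or in counting between libraries.

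Groups were taken from the sample titles: adjacent uninvolved liver, pseudoglandular (PG) tumour areas and solid/pseudopapillary (PP) tumour areas, 2 libraries each. The labels number the libraries 1 and 2 within each group and do not say that a number stands for a case, so the libraries were treated as unpaired. With 2 cases and 2 libraries per group, p-values measure only the spread between these libraries.

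Expected counts were rounded to whole numbers and tested with edgeR's quasi-likelihood method (edgeR 4.0.16, R 4.3.3) in a single model of all 6 libraries with TMM scaling. Genes were kept by filterByExpr with its default minimum count of 10 and minimum total of 15, which left 20516 genes. The fit left 3 residual degrees of freedom. Benjamini-Hochberg adjustment was applied within each of the 3 comparisons, and an adjusted p under 0.05 counted as past the threshold. Directions of the called lists did not flip under any scaling. Upper-quartile scaling moved the median log2 change of all genes in PG versus liver from −0.04 to −0.17. Fold changes are given on the log2 scale with a standard error obtained as the absolute fold change divided by the square root of F. Levels are CPM, counts scaled to the TMM-adjusted library total.

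A set of 42 lists holding 705 distinct genes (cell type markers, pathways and complexes), of which 677 passed the filter, were fixed before the data were examined, as were the groups, the tests, most alternatives and the rule for naming genes. Lists were tested with camera (limma 3.58.1) on log2 CPM at a preset correlation between genes of 0.01, again with a correlation estimated for each list, and with fry, adjusting over the 42 lists. Camera compares a list with all other genes, whereas fry asks whether the genes of a list move, on balance, one way. Counts of list members past the threshold were also adjusted over the list alone. The naming rule took, per comparison and direction, up to 10 genes past the threshold with the largest fold and no overlap between groups, or, with fewer than 3 such genes, the 5 with the smallest p among genes with an average log2 CPM of at least 2. It added 8 fixed genes (NIPBL, NACC1, INHA, ALB, KRT7, KRT19, SYP and TG) and up to 4 members of each list with the smallest p. Sex-linked genes and genes whose level can follow a donor's inherited deletion or allele (71 in all), most immunoglobulin and T cell receptor segments, pseudogenes and unnamed features were not named.

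The procedure was tested on simulated counts drawn for the 20516 genes from the observed means, dispersions and library sizes. For PP versus PG, edgeR recovered 72.7% of 64-fold changes, 25.4% of 16-fold changes and 1.49% of 4-fold changes, with 4 false calls. For PG versus liver the shares were 56.1%, 23.9% and 0%, with 2 false calls, and for PP versus liver 62.1%, 5.97% and 0%, with 5 false calls. DESeq2 recovered 97%, 95.5% and 98.5% of 64-fold changes in the same order of comparisons, with 190, 198 and 168 false calls. In each comparison camera with the preset correlation found 10 of 10 lists raised 3-fold, with 0 false calls among 10 unchanged lists of independently drawn genes. With an estimated correlation it found 8, 0 and 7 of them. Fry found 10, 9 and 10, with 0, 0 and 2 false calls. In the data the estimated correlation within a list ran from −0.05 (immediate early and heat shock) to 0.97 (erythrocytes), with 0.63 for complement and coagulation. The simulated lists had no such correlation. Their false calls therefore do not show how often an unchanged list of correlated genes would be called.

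Alternatives were other scalings (DESeq2 size factors and upper-quartile factors), no filter, a filter of 50 counts in 2 libraries, a robust dispersion prior, the replicate number as a block, DESeq2 1.42.0, limma with trend on log2(TPM + 1) or log2(TPM + 0.1) with and without a TPM filter of 1, a fit of the 4 libraries compared, a minimum log2 change of 1, and each library left out in turn. A subtraction of estimated genomic DNA, a block with crossed liver numbers and a comparison of all tumour areas with liver were added after seeing the data. The genomic DNA estimate used 388 olfactory receptor genes with over 300 coding bases, which liver does not transcribe. The subtraction used the counts per coding kilobase of the median receptor gene, 137.9 in liver 1 and 1.06 in PG 2. That rate was 0 in liver 2, PG 1, PP 1 and PP 2, which the subtraction left unchanged. The same rate gave the background counts quoted for single genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.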

Results

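Intrahepatic cholangiocarcinoma arises inside the liver and resembles bile duct epithelium. Its solid-tubulocystic variant is a rare form that is known for inhibin positivity and, in published cases, a fusion of NIPBL, which loads the cohesin ring onto DNA, with NACC1, a transcriptional co-regulator. The series holds tissue of 2 cases, in which 2 growth patterns were sampled, pseudoglandular areas (PG) with gland-like spaces and solid/pseudopapillary areas (PP), beside adjacent uninvolved liver. Each group had 2 libraries. The files give gene totals, so a fusion transcript cannot be seen in them, and the labels do not say which library came from which case.

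Library totals ran from 26.9 to 49.5 M counts. Across 20516 genes the PG libraries correlated at 0.872 with each other and the PP libraries at 0.887 (log2 CPM), whereas liver 1 and liver 2 correlated at only 0.714. Liver 2 correlated more with PG 1 (0.839), PP 1 (0.786) and PG 2 (0.762) than with liver 1, and less with PP 2 (0.694). Hemoglobin genes, the mark of red cells, made up 2.78% of the counts in liver 1 against 0.0547% in liver 2. HBA2, an alpha globin gene with a near-identical twin, stood at 9800 CPM in liver 1, 375 in liver 2 and 34.9, 102, 29.8 and 118 in PG 1, PG 2, PP 1 and PP 2. Olfactory receptor genes, which liver does not transcribe, had at least 5 counts for 352 of 388 genes in liver 1 and for 47, 62, 112, 82 and 83 in the other libraries (same order). The typical spread between libraries of a group was a coefficient of variation of 79.4%, a single value estimated from all 6 libraries, the livers included.

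**Figure D1:**
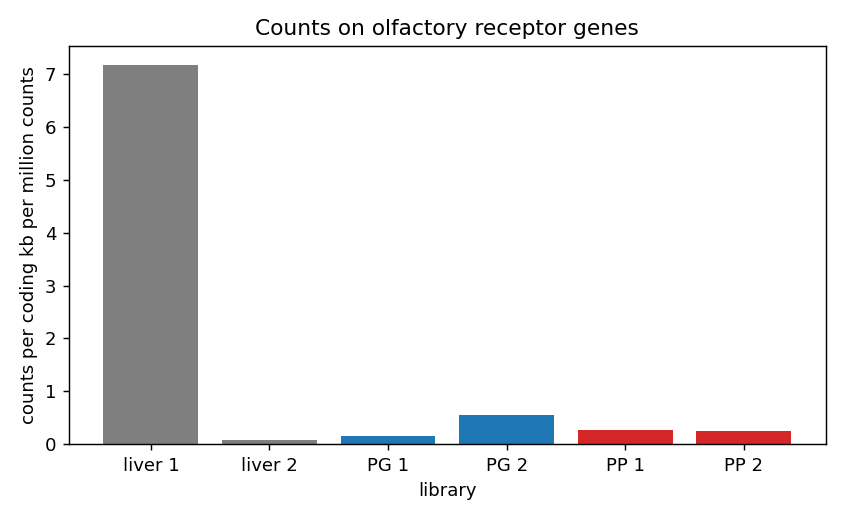
Counts on olfactory receptor genes per coding kilobase and library total in each of the 6 libraries. The value was 7.17 in liver 1 and at most 0.549 in the other libraries.

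INHA, the inhibin alpha subunit and a diagnostic marker of this tumour, was measured at 49.7 and 2.12 CPM in liver 1 and liver 2, 287 and 379 in PG and 1360 and 543 in PP. Its difference from liver was 3.68 ± 1.36 log2 units (SE, n = 2 per group) in PG and 5.19 ± 1.46 in PP, with edgeR adjusted p of 0.35 and 0.17. NIPBL stood at 326 and 421 CPM in liver, 512 and 786 in PG and 545 and 739 in PP, and NACC1 at 26.4 and 37.1, 51.5 and 18.4, and 48.9 and 25.6. ALB, encoding the most abundant hepatocyte product, kept 2480 and 2440 CPM in PG and 2170 and 2040 in PP against 4190 and 16300 in liver. KRT19, a bile duct keratin, stood at 76.5 and 11 CPM in liver, 781 and 166 in PG and 83.4 and 192 in PP, and KRT7, its usual companion, at 43 and 11.4, 50.6 and 29, and 30.9 and 4.31. SYP, a synaptic vesicle protein used to detect neuroendocrine cells, stood at 8.12 and 0.706 CPM in liver, 19.6 and 14.6 in PG and 25.6 and 21.3 in PP. TG, the thyroid hormone precursor, was not raised in tumour, with 25.9 and 9.13 CPM in liver, 3.78 and 5.89 in PG and 2.28 and 3.3 in PP. Low levels in liver 1, such as those of TG and SYP, may come in part from genomic DNA.

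**Figure D2:**
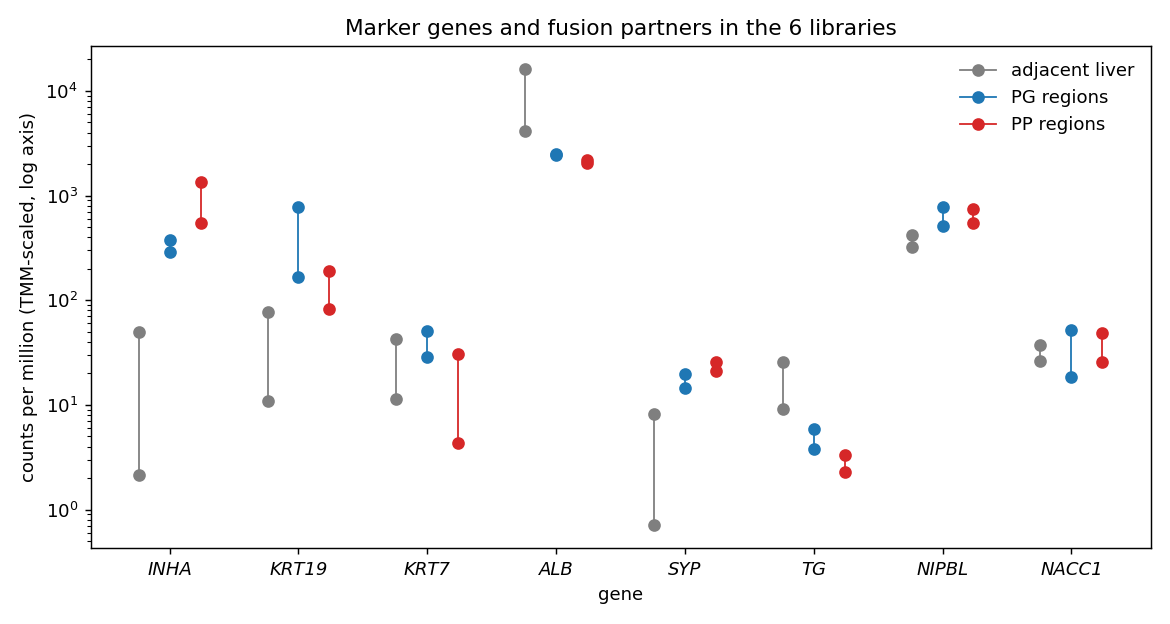
Levels of the 8 fixed genes in liver, PG and PP as CPM on a log axis. Each point is a library, and lines join the libraries of a group.

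PP and PG areas are growth patterns of the same tumour type and differ in architecture, though the labels do not show that each tumour supplied both. Gland-like growth usually goes with epithelial differentiation and solid growth with its loss, and solid sheets are often worse supplied with vessels. PP was therefore compared with PG for liver, bile duct, stromal and oxygen-related programs. With edgeR, 0 genes were higher and 0 lower at the threshold (55 and 311 at an unadjusted p under 0.05), and the smallest adjusted p was 1. DESeq2 called 17 higher and 120 lower, and limma on log2(TPM + 1) called 0 and 0.

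The genes with the smallest p were mostly lower in PP. FGL1, a secreted hepatocyte protein, stood at 40.6 and 27.8 CPM in PG and 0.234 and 0.039 in PP (log2 change −7.98 ± 1.03, SE, n = 2 per group, edgeR adjusted p = 1, as for all genes of this comparison). C9, the last component of the membrane attack complex, stood at 75.6 and 18.8 against 0.571 and 0.195 CPM (−6.95 ± 1.19). The metal-binding metallothioneins MT1G (−5.94 ± 0.98) and MT1M (−5.18 ± 0.92) were lower, and so was CCL2, which attracts monocytes, at 13.8 and 23.1 against 0.96 and 1.15 CPM (−4.12 ± 0.71). Other liver products were low in the same way, namely the acute phase proteins HP (−6.38 ± 1.59) and SAA2 (−5.86 ± 1.06), the copper carrier CP (−7.73 ± 1.62) and the lipoprotein APOA2 (−7.41 ± 1.80). ALB, by contrast, differed by −0.23 ± 1.12. CPS1, the entry enzyme of the urea cycle, varied within PG (355 and 19.4 CPM) far more than ALB did.

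The complement and coagulation list had a median log2 change of −4.29, with 17 of 18 genes lower, 10 of them past the threshold when adjusted over the list alone and 0 when adjusted over all genes (limma camera adjusted p = 6.2e-23; adjusted p = 0.44 with an estimated correlation). Hepatocyte metabolism had a median of −4.55 with 19 of 20 lower and 11 past the threshold adjusted over the list alone (limma camera adjusted p = 2e-21; adjusted p = 0.44 with an estimated correlation). Iron, metallothionein and acute phase genes had a median of −3.09 with 16 of 18 lower (limma camera adjusted p = 2e-21; adjusted p = 0.28 with an estimated correlation). In contrast, the liver transcription factors were not lower as a list (median −0.11, limma camera adjusted p = 0.83), and ONECUT1, a regulator of hepatobiliary fate, stood at 264 and 69.3 CPM in PG and 293 and 313 in PP. Among these regulators NR1I2, the xenobiotic sensor, had the largest change (−3.32 ± 1.59).

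Marker genes of liver sinusoid cells also had lower medians in PP. Sinusoidal endothelium had a median of −2.65 with 13 of 13 lower (limma camera adjusted p = 1.7e-10; adjusted p = 0.44 with an estimated correlation), with STAB2, a scavenger receptor of these cells, at 15 and 5.37 against 1.71 and 1.54 CPM. Stellate cell genes had a median of −1.92 with 9 of 11 lower (limma camera adjusted p = 6.1e-08; adjusted p = 0.28 with an estimated correlation). The lower ones included HAND2 (−3.54 ± 1.00), BMP10 (−7.47 ± 2.05), HGF, the hepatocyte growth factor (−2.05 ± 0.59), and RELN, a matrix glycoprotein (−2.85 ± 0.96). All 17 macrophage genes were lower, with a median of −0.78 (limma camera adjusted p = 6.1e-08; adjusted p = 0.44 with an estimated correlation). With genes at 0 in both libraries of a group set to the floor of 3 counts per library, the medians of the sinusoidal and stellate lists stayed at −2.65 and −1.92. Only 1 gene in each list was moved by that setting, which can hardly shift a median, so this tested little. Endothelium genes had a median of −0.66 with 14 of 15 lower (limma camera adjusted p = 6.7e-06, and 0.55 with an estimated correlation). Fibroblast and matrix genes had a median of −0.5 with 17 of 21 lower (limma camera adjusted p = 0.009, and 0.62 with an estimated correlation). Among these matrix genes DCN, the proteoglycan decorin, lay well below the median, at 79.1 and 51.9 against 14.2 and 6.65 CPM (−2.65 ± 0.69). YAP target genes had a median of −0.75 with 15 of 19 lower (limma camera adjusted p = 0.00015, and 0.44 with an estimated correlation). One of them, CCN2, a matrix-associated growth regulator, was at 72.6 and 53.3 against 24.9 and 7.47 CPM (−1.96 ± 0.70).

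Fewer genes stood higher than lower in PP. AFF3, a transcription elongation factor, was at 7.41 and 12.5 CPM in PG and 69.3 and 66.8 in PP (2.77 ± 0.59), and WNK3, a kinase that controls chloride transport, at 14.1 and 26.1 against 143 and 97.4 (2.58 ± 0.62). TM4SF4, a membrane protein of liver and intestine, stood at 23.2 and 18.2 against 289 and 100 CPM (3.23 ± 0.78), LRRC4C, a synaptic adhesion protein, at 6.51 and 7.48 against 43 and 40.8 (2.58 ± 0.70), and TRHDE, which degrades thyrotropin-releasing hormone, at 8.43 and 34.5 against 97.4 and 544 (3.90 ± 1.09). Hypoxia and glycolysis genes had a median of 0.82 with 19 of 20 higher (limma camera adjusted p = 2e-05; adjusted p = 0.55 with an estimated correlation). NDRG1, a hypoxia-induced gene, was higher in both PP libraries (90.9 and 90.6 against 185 and 227 CPM), whereas CA9, the carbonic anhydrase that marks hypoxic cells, was high only in PP 2 (1.24 and 0.342 against 1.06 and 56.4). The neuroendocrine list had a median of 0.54 with 12 of 14 higher (limma camera adjusted p = 0.00065; adjusted p = 0.44 with an estimated correlation), with SNAP25, a vesicle fusion protein, at 20.1 and 21.9 against 35.2 and 56.7 CPM. Proliferation genes were not called (median −0.41, 24 of 25 lower, though camera, which weighs log2 levels of each library, pointed higher; limma camera adjusted p = 0.65), and MKI67, the proliferation antigen, ranged from 66.1 CPM in PG 2 to 894 in PG 1. Genes of epithelial differentiation were not called either: epithelial junction (median 0.12, 12 of 22 higher, limma camera adjusted p = 0.27), biliary epithelium (median −0.15, 11 of 19 lower, limma camera adjusted p = 0.27) and keratins (median −0.71, 7 of 13 lower, limma camera adjusted p = 0.55). Of 42 lists, 22 were called at the preset correlation (3 higher, 19 lower), 0 with an estimated correlation and 0 by fry.

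PG areas were compared with liver for tumour-related programs and for markers of the liver's own cell types, without a measure of cell shares. Hepatocytes fill most of the liver, and Kupffer cells, sinusoidal endothelium and stellate cells line its sinusoids. A bile duct type tumour should lack these and carry epithelial junction and keratin genes. With edgeR, 0 genes were higher and 0 lower at the threshold (930 and 1729 at an unadjusted p under 0.05), and the smallest adjusted p was 0.0834. DESeq2 called 360 higher and 1350 lower, and limma on log2(TPM + 1) called 1 and 0. Both comparisons with liver include liver 1, the library with counts for most olfactory receptor genes. Low levels in liver 1, and falls from them in tumour, may therefore come in part from genomic DNA.

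SNHG32, a host gene of small nucleolar RNAs, had the smallest p, at 0.215 and 0.252 CPM in liver and 75.9 and 98.2 in PG (log2 change 8.53 ± 0.73, SE, n = 2 per group, edgeR adjusted p = 0.083). Its 6.6 counts in liver 1 lay below the 31 that the estimated genomic DNA would bring to its coding length, so it is not settled that it was counted alike in all libraries, and the size of its change is uncertain. The next genes had edgeR adjusted p of 0.33: TSPAN15, a tetraspanin that guides a cell surface protease, at 4.83 and 9.03 against 171 and 159 CPM (4.58 ± 0.64), PHYHIPL at 5.23 and 2.37 against 101 and 122 (4.87 ± 0.69), and CRYAB, a small heat shock protein, at 20.3 and 12.7 against 403 and 498 (4.77 ± 0.74). GRHL2, a transcription factor that maintains epithelial identity, stood at 1.2 and 1.26 against 21.6 and 29 CPM (4.36 ± 0.68). Among list genes CD24, a surface glycoprotein of bile ducts and progenitors, was at 9.01 and 3.98 against 45.8 and 209 CPM (4.29 ± 0.96), and KRT80, an epithelial keratin, at 5.17 and 1.56 against 63.2 and 110 (4.68 ± 0.95). CHGB and SCG3, granins of secretory vesicles, stood at 127 and 38.8 and at 59.6 and 38 CPM in PG against 13.3 and 0.656 and 6.74 and 0.656 in liver.

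Epithelial junction genes had a median of 1.52 with 17 of 22 higher and 1 past the threshold adjusted over the list alone (limma camera adjusted p = 0.00025; adjusted p = 0.47 with an estimated correlation; fry 0.026). DSG2, a desmosomal cadherin, and ST14, a membrane protease of epithelia, were among them (2.31 ± 0.76 and 2.20 ± 0.67). Cell cycle genes had a median of 1.55 with 23 of 25 higher (limma camera adjusted p = 0.0036; adjusted p = 0.7 with an estimated correlation; fry 0.61), led by RRM2, which makes deoxynucleotides (3.67 ± 1.30). All 16 genes of the fusion partner and cohesin list were higher, with a median of 0.8 (limma camera adjusted p = 0.0051; adjusted p = 0.52 with an estimated correlation; fry 0.14), among them the cohesin subunits STAG2 (1.48 ± 0.68) and RAD21 (1.03 ± 0.57). The biliary list as a whole was not called (median 0.15, limma camera adjusted p = 0.48). Neither were the keratins, of which 9 of 13 were lower (median −2.78, limma camera adjusted p = 0.82), nor the neuroendocrine genes, with 8 higher and 6 lower (median 1.02, limma camera adjusted p = 0.35). At an unadjusted edgeR p under 0.05, 1 keratin was higher and 0 were lower.

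STAB2 stood at 439 and 448 CPM in liver and 15 and 5.37 in PG (−5.44 ± 0.78) and MT1F at 43.7 and 58.1 against 1.83 and 1.27 (−5.03 ± 0.77), each with edgeR adjusted p of 0.33. HGF (−4.11 ± 0.64) and TENM3, a teneurin adhesion protein (−5.84 ± 0.93), shared that p. Macrophage genes had a median of −3.08 with 17 of 17 lower, all 17 past the threshold adjusted over the list alone (limma camera adjusted p = 3.2e-13; adjusted p = 0.49 with an estimated correlation; fry 0.072). C1QC, a complement subunit made by macrophages, was at 326 and 251 against 41.3 and 28.8 CPM. Sinusoidal endothelium had a median of −5.34 (limma camera adjusted p = 5.8e-10; adjusted p = 0.52 with an estimated correlation; fry 0.12), with LYVE1, its hyaluronan receptor, at 204 and 65.4 against 5.95 and 4.01 CPM. Hepatocyte metabolism had a median of −4.32 with 19 of 20 lower (limma camera adjusted p = 4.2e-08; adjusted p = 0.53 with an estimated correlation; fry 0.3). Antigen presentation genes were lower too, with a median of −2.06 (limma camera adjusted p = 7.7e-07; adjusted p = 0.52 with an estimated correlation; fry 0.14), including the class II chain HLA-DRA (−2.57 ± 0.71). Immediate early and heat shock genes had a median of −2.19 with 17 of 17 lower (limma camera adjusted p = 9.8e-07; adjusted p = 0.46 with an estimated correlation; fry 0.012), with ATF3, a stress-induced factor, at 61 and 68.7 against 6.28 and 8.28 CPM. Of 42 lists, 24 were called at the preset correlation (4 higher, 20 lower; 10 without liver 2), 0 with an estimated correlation and 2 by fry.

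**Figure D3:**
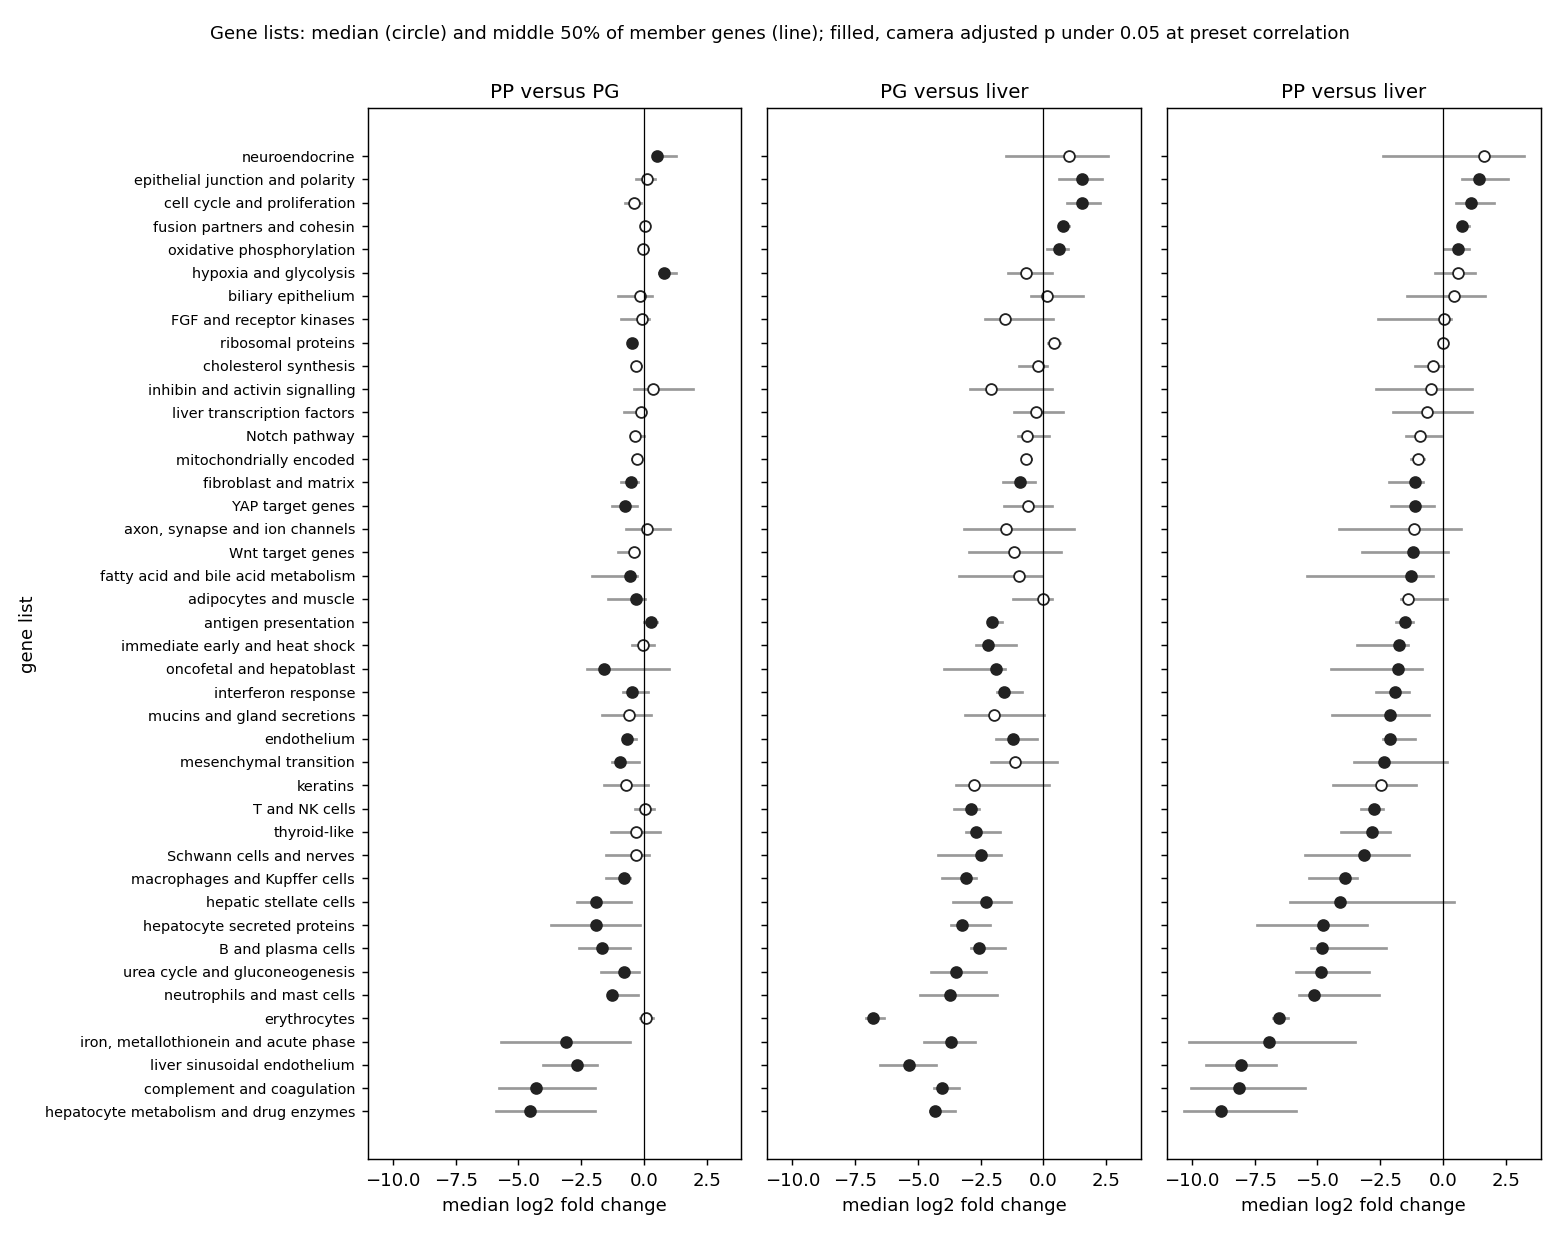
Median log2 change of the genes of each of the 42 lists in the 3 comparisons. Filled marks show lists called by camera at the preset correlation; no list was called with an estimated correlation.

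PP areas were compared with the same liver libraries. PP areas grow in solid sheets and papilla-like folds, and the comparison asks what such tissue keeps of liver and bile duct programs. With edgeR, 0 genes were higher and 0 lower at the threshold (1025 and 2321 at an unadjusted p under 0.05), and the smallest adjusted p was 0.0805. DESeq2 called 507 higher and 2103 lower, and limma on log2(TPM + 1) called 59 and 161.

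SNHG32 again had a small p, at 54.6 and 64.3 CPM in PP (log2 change 7.98 ± 0.72, SE, n = 2 per group, edgeR adjusted p = 0.081), with the same doubt about its counts in liver. GRHL2 stood at 33.2 and 45.5 CPM (5 ± 0.70), PHYHIPL at 111 and 89.7 (4.72 ± 0.68) and TSPAN15 at 107 and 106 (3.95 ± 0.63), with edgeR adjusted p of 0.081, 0.081 and 0.1. DGUOK-AS1, an antisense transcript whose reads cannot be assigned to a strand here, stood at 0 and 0.0504 CPM in liver and 9.86 and 16.4 in PP, and it too is almost absent from both livers. CD24 was at 327 and 163 CPM (5.23 ± 1.01), SNAP25 at 35.2 and 56.7 (4.47 ± 0.90) and CHGB at 258 and 153 (4.87 ± 1.38). VEGFA, the vessel growth factor, was at 548 and 331 CPM against 81 and 131 in liver (2.06 ± 0.64), and ESRP1, an epithelial splicing factor, at 119 and 189 against 26.7 and 1.51 (3.45 ± 1.18). Epithelial junction genes had a median of 1.45 with 18 of 22 higher (limma camera adjusted p = 0.00018; adjusted p = 0.28 with an estimated correlation; fry 0.0086). The keratins (median −2.45, 10 of 13 lower, limma camera adjusted p = 0.53) and the neuroendocrine genes (median 1.64, 9 higher and 5 lower, limma camera adjusted p = 0.065) were not called. Neither was the biliary list as a whole (median 0.46, 11 higher and 8 lower, limma camera adjusted p = 0.79). The liver transcription factors were not called either (median −0.64, 4 higher and 9 lower, limma camera adjusted p = 0.54). Of the keratins, 1 was higher and 0 were lower at an unadjusted edgeR p under 0.05.

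FGL1 had the largest change among the genes with the smallest p (−11.93 ± 1.19), followed by MT1G (−10.36 ± 1.16), COLEC10, a liver collectin (200 and 84.4 against 0.727 and 0.312 CPM, −8.10 ± 0.91), STAB2 (−8.09 ± 0.88) and H19, an imprinted noncoding RNA (605 and 227 against 1.95 and 2.46 CPM, −7.56 ± 0.85), all with edgeR adjusted p of 0.081. IGF2, the imprinted growth factor beside H19, was lower as well (−8.32 ± 1.19). CLEC4G, a lectin of sinusoidal endothelium, had 123 and 67.3 CPM in liver and 0 in both PP libraries. CD5L, secreted by Kupffer cells, stood at 192 and 91.5 against 0.0519 and 0.0195 CPM, and SLCO1B1, a hepatocyte uptake transporter, at 21.4 and 449 against 0.026 and 0.0585. The sinusoidal and stellate lists had medians of −8.04 and −4.08 (limma camera adjusted p = 1.5e-11 and 0.00026; adjusted p = 0.41 and 0.28 with an estimated correlation; fry 0.049 and 0.0086). Of 13 sinusoidal genes 12 were lower and 1 higher. Of 11 stellate genes 7 were lower and 4 higher, with 6 and 1 past the threshold adjusted over the list alone. Both medians stayed the same with genes at 0 set to that floor, a setting in which the lists were not tested. Again only 1 gene in each list was moved, so the unchanged medians say little. Hepatocyte metabolism had a median of −8.84 with 17 genes past the threshold adjusted over the list alone (limma camera adjusted p = 2.7e-13; adjusted p = 0.41 with an estimated correlation; fry 0.099). Complement and coagulation had a median of −8.11 (limma camera adjusted p = 2.7e-13; adjusted p = 0.41 with an estimated correlation; fry 0.079). Macrophage genes had a median of −3.9 with 17 of 17 lower (limma camera adjusted p = 9.6e-15; adjusted p = 0.41 with an estimated correlation; fry 0.034). B and plasma cell genes had a median of −4.83 (limma camera adjusted p = 3e-06; adjusted p = 0.41 with an estimated correlation; fry 0.11), with JCHAIN, the joining chain of secreted antibodies, at 55 and 39.1 against 0.96 and 0.0585 CPM. MYC, a growth regulator listed with the Wnt targets, stood at 76 and 227 CPM in liver and 2.31 and 11 in PP (−4.51 ± 0.98). ALB differed by −2.28 ± 1.17. Of 42 lists, 29 were called at the preset correlation (4 higher, 25 lower; 15 without liver 2), 0 with an estimated correlation and 6 by fry.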

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

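The tests of depth in liver 1, of liver carried into PG and of scaling were chosen after their results were seen, and the fit of the 4 tumour libraries alone was added after the data were seen, with its bounds set before its own result.

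Among 304 named genes, 2 moved in opposite directions against liver in the growth patterns, with every PG library below and every PP library above both liver libraries. AFF3, a transcription elongation factor, stood at 32.2 and 35.8 CPM in liver, 7.41 and 12.5 in PG and 69.3 and 66.8 in PP (PP versus PG 2.77 log2 units). WNK3, a kinase of chloride transport, stood at 32.6 and 49.2 in liver, 14.1 and 26.1 in PG and 143 and 97.4 in PP (2.58). The difference between the patterns did not pass the threshold for either gene (edgeR adjusted p = 1), and a search of 304 genes in 6 libraries can give such an order by chance.

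Liver 1 stood apart from liver 2, with a correlation of 0.714 and far more hemoglobin counts. Olfactory receptor genes had 13.1 times as many counts per coding kilobase and library total as in the next highest library, so genomic DNA is a candidate explanation. The estimated share of genomic DNA was 25.8% of the counts from the mean receptor gene, on which that ratio also rests, and 18.4% from the median gene. The subtraction reported below used the smaller estimate. Blood as the whole cause is argued against by the 352 receptor genes with at least 5 counts, since blood brings no such reads, though blood in addition to DNA stays open. Lower depth is argued against by the totals, with a ratio of liver 1 to liver 2 of 0.938. Genomic DNA as the whole cause is argued against by 43 hepatocyte genes, whose share of the liver level is defined below. Their median share in PG 1 was 37.4% of liver 1 but 5.27% of liver 2, so they stood far lower in liver 1. In PG 2 the median share was 3.73% and 0.629%. DNA at the estimated 25.8% of the counts would take only that share from other genes. DNA in addition to another difference stays open. Differences between the livers of the cases were not tested.

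Hepatocyte and complement genes were lower in PP than in PG. Scaling is argued against: a library factor moves all genes alike, whereas the median of these 58 genes lay −3.21 log2 units from that of all genes, and their upper quartile −0.88. Adjacent liver carried into the PG areas may contribute and cannot be told apart from hepatocyte-like expression of the tumour cells. The share of the liver level was taken as PG less the PP mean, divided by liver less the PP mean. Only genes measured well in liver and far lower in PP were used, which kept 43 of the 58 and left out ALB. The median share of these hepatocyte genes, among them HP at 1030 and 353 CPM, was 8.75% in PG 1 and 1.03% in PG 2. It was 37.4% and 3.73% against liver 1 alone and 5.27% and 0.629% against liver 2 alone. For 25 sinusoidal and Kupffer genes the median share against both livers was 0.413 (95% range 0.299 to 0.574) and 0.224 (0.0358 to 0.823) times as large. These ranges come from resampling genes within a library and do not measure the spread between tissue pieces. The ratio was 0.0818 and 0.0365 against liver 1 alone but 1.29 and 0.745 against liver 2 alone, so the choice of liver keeps the question open.

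Tumour libraries with the same number correlated across patterns at 0.918 for both pairs, but PG 2 and PP 1, with different numbers, also reached 0.904, against 0.866 for PG 1 and PP 2 and 0.872 and 0.887 within the patterns. Depth is argued against, since after thinning to a common total the same-number pairs still exceeded the same-pattern pairs by 0.04 (0.915 against 0.875, with 0.881 for pairs sharing neither). Whether the number marks a shared case cannot be told from that fit: in edgeR the number and the pattern each called 0 genes among the 4 tumour libraries, a difference of 0, while 2413 and 550 genes had an unadjusted p under 0.05. The bound against a shared case, no more calls by number than by pattern, was met only because neither term called any gene, so it was uninformative. The order of the unadjusted counts may reflect a shared case.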

How the results depend on the processing

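The subtraction of genomic DNA, the block with crossed liver numbers, the block in the tumour libraries alone and the lists with a library left out were chosen after the data were seen.

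edgeR's counts of 0 higher and 0 lower genes (at an unadjusted p under 0.05, 55 and 311 in PP versus PG, 930 and 1729 in PG versus liver, 1025 and 2321 in PP versus liver) held under both other scalings, the stricter filter, the robust prior, the fit of 4 libraries, limma on TPM + 1 without a filter, and subtraction of genomic DNA. The minimum change can only remove calls, so with 0 calls it tested nothing. In the same order of comparisons, DESeq2 gave 17 and 120, 360 and 1350, and 507 and 2103. Without a filter edgeR gave 28 and 213, 300 and 1021, and 409 and 1538. limma on log2(TPM + 1) gave 0 and 0, 1 and 0, and 59 and 161, and on log2(TPM + 0.1) 0 and 0, 3 and 0, and 41 and 128. The cause was not tested. In counts simulated for the filtered genes, DESeq2 made 168 to 198 false calls and edgeR without a filter 4, 5 and 5. The unfiltered fit of the data held 37577 genes, and those that the filter removes were not simulated. The few false calls therefore do not speak for edgeR's calls without a filter.

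With the replicate number as a block, edgeR called 0 and 0 genes in each comparison (unadjusted 31 and 221, 1113 and 1344, 1203 and 1994). Crossing the liver numbers gave 4 and 142 in PP versus liver, and 0 and 0 in PP versus PG and PG versus liver. Deviations of the numbered libraries from their group correlated at −0.086 (liver and PG), −0.12 (liver and PP) and 0.28 (PG and PP), so the numbers were not shown to pair liver with tumour.

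With a library left out, the lone sample of its group was assumed to vary like the others. PP versus PG stayed at 0 and 0. PG versus liver ranged over 0 to 2 higher and 0 to 3 lower, the highest without liver 2. PP versus liver ranged over 0 to 23 higher and 0 to 209 lower: 23 and 156 without liver 2, 7 and 120 without PG 1, and 10 and 209 without PG 2. The cause was not tested.

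Lists called by camera at the preset correlation (22, 24 and 29) numbered 0, 0 and 0 with an estimated correlation, whose smallest adjusted p were 0.28, 0.46 and 0.28, and 0, 2 and 6 by fry. With a library left out they ranged over 17 to 24, 10 to 25 and 15 to 29; 10 and 15 were the counts without liver 2. The cause was not tested.

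Of the values of named genes under the alternatives, 3575 of 3723 in PP versus PG, 3319 of 3542 in PG versus liver and 3070 of 3546 in PP versus liver kept direction and side of the threshold; 70, 205 and 464 passed it only there. A further 78, 18 and 12 values had the opposite sign without being called, and 0 called values reversed. In simulated counts edgeR found 72.7%, 56.1% and 62.1% of 64-fold changes but 25.4%, 23.9% and 5.97% of 16-fold and 1.49%, 0% and 0% of 4-fold changes; the cause of the 0 calls was not tested.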

Other observations

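The comparison of all tumour areas with liver, with all its alternatives, and the search for genes absent from liver were chosen after the data were seen.

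For the mean of PG and PP against liver, edgeR placed 21 genes higher and 342 lower at the threshold. The tumour libraries come from 2 cases and are not independent, which the fit ignores, so these p-values cannot be taken at face value. GRHL2, an epithelial transcription factor, was higher in 4 of 4 tumour libraries than in both livers (4.68 ± 0.66, SE, edgeR adjusted p = 0.041). So were PHYHIPL (4.79 ± 0.66, adjusted p = 0.04), the zinc finger gene ZNF726 (4.85 ± 0.82, adjusted p = 0.046) and the heat shock protein CRYAB (4.30 ± 0.69, adjusted p = 0.046). LRAT, which esterifies retinol, was higher as well (4.38 ± 0.74, adjusted p = 0.046), against the direction of the stellate list to which it belongs. SAA1, an acute phase protein, was lower in 4 of 4 (−8.97 ± 1.19, adjusted p = 0.038). INHA did not pass the threshold (4.44 ± 1.35, edgeR adjusted p = 0.13). The counts depended on single libraries, with 0 and 0 without PP 1, 0 and 0 without PP 2, 2 and 53 without PG 1, 1 and 3 without PG 2, 42 and 265 without liver 1 and 591 and 4555 without liver 2. They were 0 and 0 in edgeR with genomic DNA subtracted or with the replicate block, 23 and 359 with the block and crossed liver numbers, and 750 and 2476 in DESeq2. Without a filter edgeR gave 544 and 3495. With limma they were 142 and 189 on log2(TPM + 1), 82 and 104 on log2(TPM + 0.1), and 1 and 0 on log2(TPM + 1) without a filter. In the unaltered fit 1229 and 3092 genes had an unadjusted p under 0.05.

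A search for genes with at least 200 counts in each tumour library and at most 7 in each liver library found 3 genes. SNHG32 had 6.6 and 5.2 expected counts in liver, 2694.2 and 4020 in PG and 2104.7 and 3295.1 in PP. CDSN, a skin adhesion protein, was listed at 0 in both liver libraries and had 290.1 and 220.4 in PG and 463 and 300.2 in PP. DGUOK-AS1 had 0 and 1, 344 and 990, and 380 and 842. The genomic DNA estimated for liver 1 would bring 31 counts to a gene with the coding length of SNHG32 and 219 to one with that of CDSN. Whether all libraries were counted against the same annotation is not given in the sources used here. Of 16037 coding genes for which that estimate was at least 100 counts, 13 were at 0 after rounding in liver 1 and at least 100 in each of the other 5 libraries.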
